A study of Mus musculus with 18 samples.

How the data were processed

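RNA sequencing was done on mouse embryos and endometrial tissue kept together or apart ex vivo for 24 h with celecoxib or DMSO. Per the labels, 24 embryos from 3 donor mice were divided among 4 groups, and each embryo library came from 6 pooled embryos lysed in the buffer of a SMART-Seq kit. Each endometrial library came from 3 implantation sites of 1 recipient mouse, cut into 500 µm pieces, combined and extracted with TRIzol. Libraries were made from polyadenylated RNA of B6D2F1/J animals with a SMART-Seq mRNA low-input kit, which amplifies full-length cDNA. Replicates are therefore pools of embryos or tissue, not single animals' embryos, and an amplified low-input library measures scarce transcripts with more error than its depth alone implies.

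The deposited tables hold 1 value per gene and library in 2 units: expected counts and TPM. Per the labels and the values themselves, the deposited expected counts are estimated counts, in which a read that matches several genes is shared among them, so 29.0 to 41.5% of the values were not whole numbers; they were rounded before the count models. The deposited TPM columns each sum to 1000000. The build named in the submitters' processing notes is GRCm38; the aligner, the quantification tool, the annotation release and the strandedness are not given in the sources used here. Gene symbols and positions were taken from GENCODE vM21 on the same build: 34582 of 34866 gene identifiers matched without their version and 284 had no symbol. Genes that share sequence (MHC class Ib, olfactory receptor, prolactin, Rhox, cathepsin-like, immunoglobulin and Sprr2 families) or overlap on opposite strands have counts that depend on steps not described.

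Columns were joined to samples by the names in the labels. Of 18 labelled samples, 11 had columns that match a label: 7 embryo and 4 endometrial libraries. For the other 7 libraries the columns (14, counts and TPM) match no label, and they were not used in any step; the comparison of implantation sites with the tissue between them was therefore not analysed here. The planned model held a term for the table a library came from. All libraries used stand in 1 table per tissue, so this term drops out. The replicate numbers were treated as names only. The labels divide 24 embryos of 3 donors among 4 groups. At 6 embryos per library this fills 1 library per group, so the embryo libraries used came from more than 1 such division. Libraries of 1 division would share donors across groups, but the labels do not say whether libraries of the same number do. Tests between embryo groups may therefore leave a pairing unused. Groups were co-cultured or solely cultured embryos with DMSO or celecoxib, and implantation sites with DMSO or celecoxib.

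Totals per library, in units of 1000000 estimated counts, were 41.3 and 40.8 for solely cultured DMSO, 52.4 and 49.3 for solely cultured celecoxib, 35.4 and 44.3 for co-cultured DMSO, 47.8 for co-cultured celecoxib, 59.6 and 62.8 for DMSO and 54.3 and 47.3 for celecoxib implantation sites (libraries 2 and 3 in each, 2 for co-cultured celecoxib). At this depth counting error is small for genes above a few CPM, and the spread between libraries sets the precision. Mitochondrial transcripts took 2.19 to 3.47% of embryo and 1.71 to 2.26% of endometrial counts, and the 10 most abundant genes 3.9 to 5.95%. The scaling factors of TMM ran from 0.875 to 1.28 in embryos, with the highest in co-cultured DMSO library 3, and from 0.985 to 1.01 at implantation sites.

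Differential expression was tested in R 4.3.3 on the rounded estimated counts with edgeR 4.0.16: filterByExpr, TMM scaling, 1 mean per group, robust dispersions, and the quasi-likelihood F test with 3 residual degrees of freedom in embryos and 2 in endometrium. P-values were adjusted over all tested genes by Benjamini and Hochberg, with a threshold of 0.05. All adjusted p-values of genes come from this test unless DESeq2 or limma is named. The standard errors are the fold change divided by the square root of F and are approximate. The comparisons were co-culture against sole culture with DMSO and with celecoxib, celecoxib against DMSO in co-culture, in sole culture and at implantation sites, and the interaction. The co-cultured celecoxib group has 1 library, and its tests use the spread of the other groups. No group has 3 libraries, so samples were not reassigned at random.

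The comparisons, gene lists and rule for naming genes were fixed before the data were examined. The rule took genes with plain symbols that passed, with a mean log2 CPM of 3 or more and no overlap between the groups' libraries. Of these it named the 6 largest changes per direction in the main comparisons (co-culture with DMSO, celecoxib in co-culture and at implantation sites) and 3 in the others. Where fewer than 3 passed in a direction, the genes with the smallest p were given up to 3. It also named up to 4 members of each list by smallest p, and Ptgs2, Ptgs1 and Akt1. List members named with no call are given as values. Of 30 lists, 25 were tested in embryos and 24 in endometrium: naive pluripotency, post-implantation epiblast, primitive and visceral endoderm, parietal endoderm, trophectoderm, trophoblast giant cells and invasion, prostaglandin, PI3K-AKT-mTOR, FOXO targets, hypoxia and glycolysis, cholesterol synthesis, unfolded protein response, ATF4, p53 targets, cell cycle, immediate early, NRF2 and aryl hydrocarbon receptor, uterine epithelium, stroma, leukocytes, erythroid cells, endothelium, smooth muscle, decidualization, attachment and receptivity, inflammatory, interferon, matrix, angiogenesis and embryonic cells. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists of a tissue; the estimated correlation was also run. Counts of called members, over all genes and adjusted over the list alone, are given for co-culture with DMSO and for most lists at implantation sites. For the other comparisons they are given for some lists only. Lists of lysosomal enzymes and of fatty acid oxidation were added after the gene values were seen and are given in the closing part. A fold against a group at 0 is a bound at a floor of 3 counts over the group.

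The alternatives were DESeq2 size factors, library totals, no filter, a stricter filter (10 counts in each library of a compared group), a term for the replicate number, the compared groups alone, leaving out each library in turn, DESeq2 1.42.0, and limma on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of 1 or more, or for all genes. The correlations between comparisons were set against 30 simulated data sets without change. These drew each gene independently, so their ranges leave out variation that genes share. The pipeline was tested on simulated data with 200 changed genes per comparison. These were drawn from the more abundant genes, so recovery of scarce genes was not measured. The lone co-cultured celecoxib library was given the same spread as the others, which the tests also assume. At a log2 fold change of 1 the edgeR test recovered 20, 6, 18, 3 and 55% of changed genes, and at 2 it recovered 83, 62, 77, 57 and 94%, in the order co-culture with DMSO, celecoxib in co-culture, celecoxib in sole culture, co-culture with celecoxib and implantation sites, with no wrong sign. A list shifted by 0.5 was recovered in all 5, and 1 unshifted list was called, for celecoxib in sole culture. Genes were drawn independently here too, so this gives no false-call rate for lists whose genes vary together. DESeq2 recovered 16 to 82% of the smaller changes with 43 to 73 false calls per comparison, against 4 to 14 false calls for edgeR.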

Results

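Mouse embryos were cultured ex vivo for 24 h, either alone or on endometrial tissue, with celecoxib, a selective inhibitor of the prostaglandin-producing enzyme COX-2, or with its solvent DMSO. The analysis used 7 embryo libraries (solely cultured with DMSO, n = 2, and with celecoxib, n = 2; co-cultured with DMSO, n = 2, and with celecoxib, n = 1) and 4 endometrial libraries from implantation sites (n = 2 per treatment). In units of 1000000 estimated counts, the embryo libraries held 35.4 to 52.4 and the endometrial libraries 47.3 to 62.8. At least 1 count was found for 21877 to 24472 genes in the 3 co-cultured embryo libraries and for 19210 to 21444 in the 4 solely cultured ones. Libraries of 1 group correlated across genes with r of 0.953 to 0.968 in embryos (3 pairs) and 0.946 to 0.972 in endometrium (2 pairs). Pairs from different groups reached 0.966 and 0.949, and co-cultured DMSO library 2 correlated with the co-cultured celecoxib library (0.954) as closely as with its own replicate (0.953).

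On the first principal component of the embryo libraries (47.6% of the variance), the solely cultured libraries lay between -93.93 and -24.17 and the co-cultured DMSO libraries at 109.4 and 131.7. The single co-cultured celecoxib library lay between them, at 39.29. At implantation sites the first component (47.5%) held the DMSO libraries at -77.4 and -27.9 and the celecoxib libraries at 48.0 and 57.3, while the second (34.3%) held the DMSO libraries apart, at 48.3 and -78.3. Values below are log2 fold changes ± approximate standard errors unless another unit is named, and group levels are mean counts per 1000000 (CPM) ± SD between libraries.

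**Figure D1:**
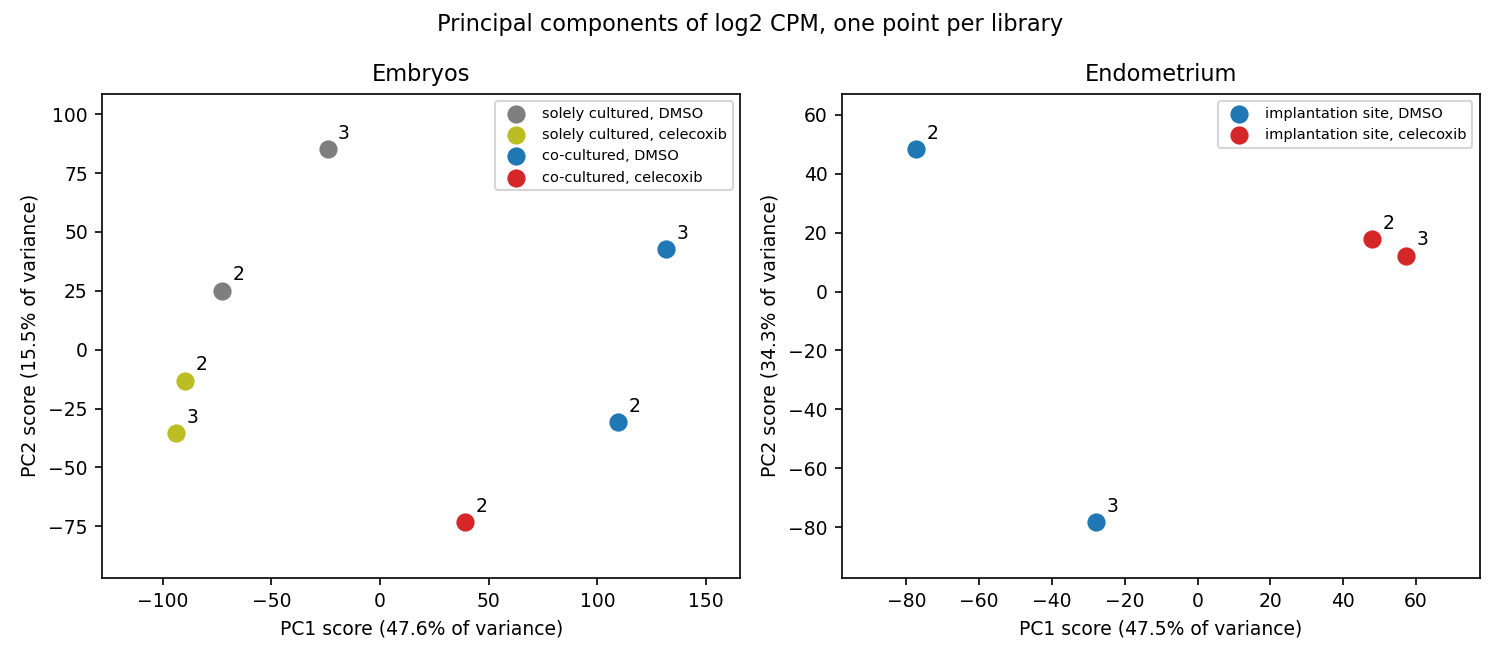
Principal components of the 7 embryo libraries (left) and the 4 implantation-site libraries (right), with the first component on the horizontal axis and the second on the vertical axis. Each point is 1 library, coloured by group; the first component holds 47.6% of the variance in embryos and 47.5% at implantation sites.

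Ptgs2, which encodes COX-2, the target of celecoxib, was near the floor in embryos and abundant at implantation sites. Its group means stayed under 1.4 CPM in all 4 embryo groups, against 306 ± 5.89 CPM at DMSO and 193 ± 50.2 CPM at celecoxib implantation sites. The celecoxib difference at implantation sites did not pass the test (-0.67 ± 0.18, adjusted p = 0.170), nor did any embryo comparison of Ptgs2 (co-culture with DMSO 1.04 ± 1.31, adjusted p = 0.616). Ptgs1, which encodes the constitutive enzyme COX-1, did not pass either (0.11, adjusted p = 0.866 at implantation sites; -0.14, adjusted p = 0.907 for co-culture with DMSO). Akt1, a kinase gene of the PI3K pathway, was close to level between co-cultured and solely cultured DMSO embryos (-0.25, adjusted p = 0.401) and between treatments at implantation sites (0.04, adjusted p = 0.913).

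Co-culture was accompanied by broad differences between DMSO embryos. Adh1, an alcohol dehydrogenase that also oxidizes retinol (ENSMUSG00000074207.10, chromosome 3, 138260991 to 138290698), fell by 7.65 ± 0.43, from 431 ± 45.0 CPM in solely cultured to 2.15 ± 0.25 CPM in co-cultured embryos (adjusted p = 0.000194). Also lower were Pramel6, a gene of early embryos and naive pluripotent cells (-6.42 ± 0.94), and Fam151a (-5.15 ± 0.23, 216 ± 28.5 to 6.07 ± 0.21 CPM). They were joined by the pantetheinase Vnn1 (-4.95 ± 0.37), the water and glycerol channel Aqp9 (-4.89 ± 0.29) and the calcium channel Trpv5 (-4.85 ± 0.42). The largest of the named increases were in H2-T23, an MHC class Ib gene (ENSMUSG00000067212.8, chromosome 17, 36029773 to 36032855; 3.85 ± 0.48, 3.85 ± 1.63 to 55.5 ± 30.4 CPM), the olfactory receptor gene Olfr1167 (3.53 ± 0.34) and the Rho exchange factor Arhgef40 (3.52 ± 0.35). They were followed by Rpgrip1 (3.37 ± 0.40), the ubiquitin ligase Prkn (3.20 ± 0.35) and the growth-arrest gene Gadd45a (3.14 ± 0.36, 4.93 ± 1.25 to 43.4 ± 14.6 CPM). H2-T23 and Olfr1167 belong to families of similar sequence, whose counts depend on how reads were shared among members. Without co-cultured DMSO library 3, Pramel6 missed the threshold (adjusted p = 0.0611).

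**Figure D2:**
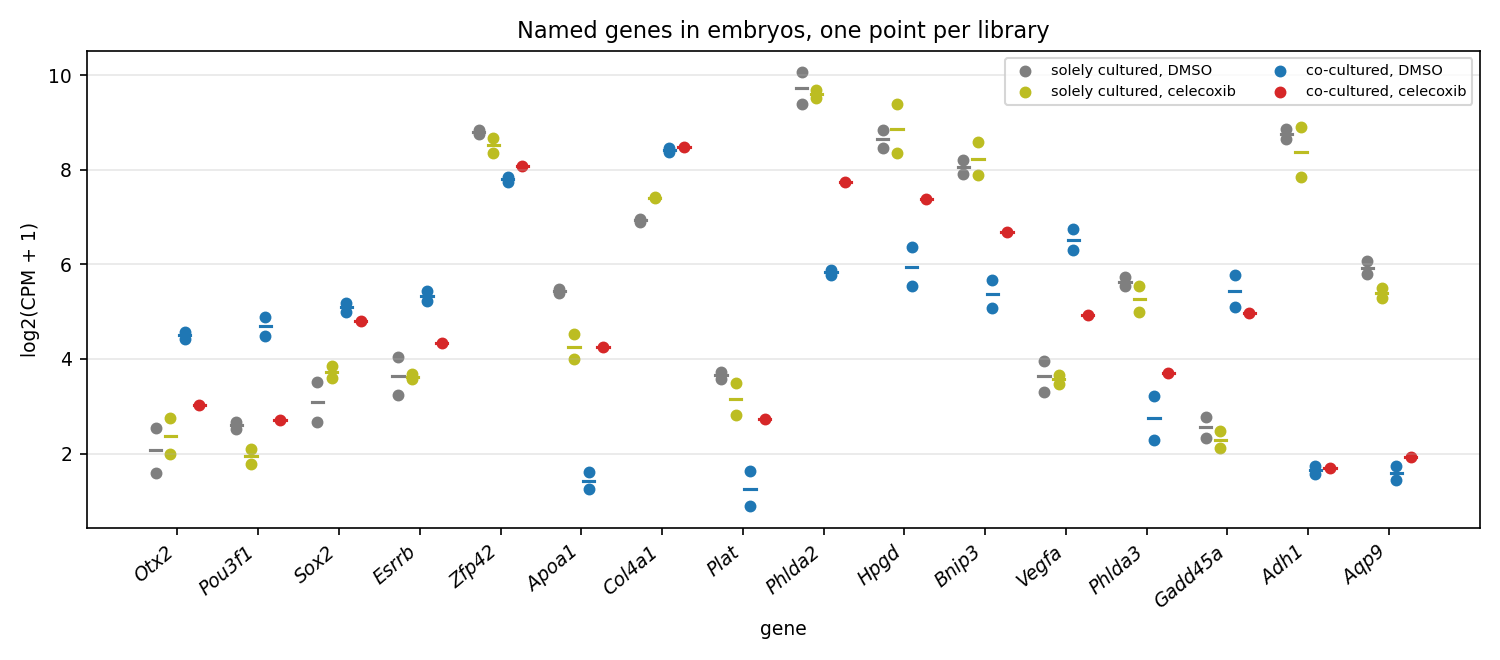
Levels of 16 genes in the 7 embryo libraries, as log2(CPM + 1) on the vertical axis and by culture and treatment on the horizontal axis. Each point is 1 library and each short line a group mean; co-cultured celecoxib is a single library, and Adh1 stood at 431 CPM in solely cultured against 2.15 CPM in co-cultured DMSO embryos.

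Of 19455 genes tested, 1122 were higher and 2021 lower in co-cultured DMSO embryos (edgeR quasi-likelihood test, n = 2 per group, 3 residual degrees of freedom; 35.7% higher). With library totals as the scale, the median of all genes moved up by 0.287, and 1693 genes were higher and 1214 lower (58.2% higher), so which direction held more genes depended on the scaling. Without solely cultured DMSO library 2 or 3 the count dropped to 1190 or 1329, and DESeq2 called 4744.

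Among the lineage lists, 5 of 19 post-implantation epiblast and 6 of 17 parietal endoderm genes rose and 4 of 22 trophectoderm genes fell, but no list passed the list test. Of 19 post-implantation epiblast genes, 5 rose and 0 fell, among them Otx2 (2.66 ± 0.51), Pou3f1 (2.31 ± 0.34) and Sox2 (2.07 ± 0.35), transcription factors of the epiblast, and the Nodal co-receptor Tdgf1 (0.97 ± 0.23). Adjusted over the list alone, 6 were higher and 1 lower. Of 14 naive pluripotency genes, 4 rose and 3 fell (8 and 3 over the list alone), with Esrrb (1.72 ± 0.33) and Tbx3 (1.01 ± 0.23) higher and Zfp42 (-1.01 ± 0.20) and Tfcp2l1 (-0.99 ± 0.19) lower. Of 17 parietal endoderm genes, 6 rose and 1 fell (7 and 1 over the list alone), with the basement membrane genes Col4a2 (1.74 ± 0.21), Col4a1 (1.49 ± 0.18) and Lamc1 (1.55 ± 0.21) higher. The plasminogen activator Plat was lower (-2.96 ± 0.52). Of 24 primitive and visceral endoderm genes, 5 rose and 1 fell, over all genes and over the list alone, with Spink1 (2.79 ± 0.41), Amot (1.69 ± 0.29) and Gata6 (1.02 ± 0.24) higher and the apolipoprotein gene Apoa1 lower (-4.61 ± 0.35). Their median was 0.43 and the list test pointed up. Their fitted mean was -0.01, or 0.27 with library totals, and 0.15 with the 1 member at 0 in a group set at its bound.

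Of 22 trophectoderm and extraembryonic ectoderm genes, 0 rose and 4 fell (2 and 6 over the list alone): the keratins Krt18 (-1.42 ± 0.22) and Krt8 (-1.21 ± 0.23), Ascl2 (-2.08 ± 0.36) and Id2 (-1.78 ± 0.39). The mean of this list was -0.12 and turned to 0.17 with library totals, with 2 genes higher and 4 lower. Of 21 genes of trophoblast giant cells and invasion, 2 rose and 4 fell (2 and 5 over the list alone), with Plau, another plasminogen activator, higher (1.99 ± 0.37). Phlda2, an imprinted gene that restrains placental growth (-3.95 ± 0.28), Lgals3 (-1.73 ± 0.28) and the amino acid transporter Slc38a4 (-1.58 ± 0.29) were lower. No lineage list passed the list test (adjusted p = 0.473 for naive pluripotency, 0.473 for epiblast, 0.621 for primitive and visceral endoderm, 0.107 for parietal endoderm, 0.570 for trophectoderm and 0.157 for trophoblast giant cells). Of the lineage genes named here and above, Zfp42, Tbx3, Gata6, Krt8, Id2 and Plau missed the threshold without solely cultured DMSO library 2 (adjusted p = 0.0518 to 0.134). Without library 3 of that group they missed it too, with Esrrb, Tfcp2l1, Otx2, Tdgf1, Amot and Slc38a4 (0.0536 to 0.142). Gata6 was also lost without co-cultured DMSO library 2 (0.0674) and Tdgf1 without library 3 (0.0580).

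Of 19 p53 target genes, 1 rose and 9 fell, over all genes and over the list alone, and the list passed the list test (mean -0.90, median -0.76, 15 of 19 negative, adjusted p = 0.00262). With an estimated correlation between genes its adjusted p = 0.841, and with library totals 1 rose and 7 fell (mean -0.62, adjusted p = 0.00303). The apoptosis-related Phlda3 (-3.01 ± 0.39, 48.8 ± 4.58 to 6.07 ± 3.11 CPM), the death receptor Eda2r (-2.79 ± 0.43), Trp53inp1 (-1.61 ± 0.20) and Ccng1 (-1.44 ± 0.19) fell. Of 28 cell cycle genes, 0 rose and 6 fell, over all genes and over the list alone; with library totals 1 rose and 2 fell, and the list mean of -0.26 turned to 0.03. Among those lower were the replication genes Mcm7 (-1.01 ± 0.19), Mcm6 (-0.82 ± 0.19) and Cdc6 (-0.97 ± 0.21) and the anaphase activator Cdc20 (-1.13 ± 0.22). The cell cycle list did not pass (adjusted p = 0.0733). Of 16 immediate early genes, 2 rose and 0 fell (3 and 2 over the list alone; list adjusted p = 0.570), Egr1 (2.70 ± 0.48) and Ier3 (2.19 ± 0.32). Without solely cultured DMSO library 2, Mcm7, Cdc20, Mcm6 and Egr1 missed the threshold (adjusted p = 0.0615 to 0.111), and without library 3 these 4 and Cdc6 did (0.0522 to 0.107).

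Of 19 genes of prostaglandin synthesis and signalling, 1 rose and 3 fell, over all genes and over the list alone. Hpgd, the main prostaglandin-degrading dehydrogenase, fell by 2.68 ± 0.40 (406 ± 75.7 to 63.4 ± 25.5 CPM), as did the prostaglandin E synthase gene Ptges (-1.82 ± 0.36) and Akr1b3 (-0.71 ± 0.20; adjusted p = 0.0528 with DESeq2 size factors). The prostaglandin transporter Slco2a1 rose (1.40 ± 0.32). The median (-0.12) and the list test pointed down and the mean (0.34, or 0.16 with 1 member at its bound) up (adjusted p = 0.974). Of 26 PI3K-AKT-mTOR components, 2 rose and 2 fell (3 and 2 over the list alone), Igf1r (2.01 ± 0.48) and Foxo1 (1.27 ± 0.27) higher and the subunit genes Pik3cb (-1.38 ± 0.24) and Pik3r2 (-1.07 ± 0.25) lower. Here too the median (-0.22) and the test pointed down and the mean (0.10) up (adjusted p = 0.621). Of 20 FOXO target genes, 3 rose and 3 fell (5 and 4 over the list alone; median 0.20, adjusted p = 0.937). Gadd45a was higher, and Ccng2 (-2.88 ± 0.44), the mitophagy receptor Bnip3 (-2.70 ± 0.31) and the superoxide dismutase Sod2 (-1.82 ± 0.22) were lower. Without solely cultured DMSO library 2 or 3, Ptges, Slco2a1, Akr1b3, Foxo1, Pik3r2 and Igf1r missed the threshold (adjusted p = 0.0623 to 0.241 and 0.0553 to 0.125). Without co-cultured DMSO library 2 this held for Foxo1 and Igf1r (0.0517 and 0.0844), and without library 3 for Slco2a1, Akr1b3 and Pik3r2 (0.0639, 0.0654 and 0.0569).

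Of 25 hypoxia and glycolysis genes, 1 rose and 6 fell (2 and 8 over the list alone): the angiogenic factor Vegfa rose (2.97 ± 0.31, 11.7 ± 4.09 to 91.7 ± 19.8 CPM), while Bnip3, Ndrg1 (-2.02 ± 0.23) and the enolase Eno1 (-1.09 ± 0.20) fell. Among 21 cholesterol synthesis genes, 2 rose and 5 fell, over all genes and over the list alone, with Dhcr24 (1.49 ± 0.34) and the regulator Srebf2 (1.17 ± 0.26) higher and Insig1 (-1.51 ± 0.32) and Fdft1 (-0.97 ± 0.21) lower. The endoplasmic reticulum genes Herpud1 (-1.43 ± 0.27), Pdia4 (-1.18 ± 0.18) and Hspa5 (-0.97 ± 0.27) fell among 18 genes of the unfolded protein response, of which 0 rose (0 and 5 over the list alone). With library totals the means of these 3 lists changed sign, from -0.22 to 0.06 for hypoxia (2 higher, 6 lower), -0.17 to 0.10 for cholesterol (2 and 3) and -0.28 to 0.02 for the unfolded protein response (1 and 2). Of 22 ATF4 stress response genes, 6 rose and 3 fell (8 and 3 over the list alone), with Atf5 (2.34 ± 0.39), Nupr1 (adjusted p = 0.00389) and the amino acid transporter Slc7a5 (1.38 ± 0.27) higher and the serine synthesis gene Phgdh lower (-1.32 ± 0.24). Among 18 NRF2 and aryl hydrocarbon receptor targets, 1 rose and 3 fell (1 and 4 over the list alone). Slc7a11 was higher (1.52 ± 0.39) and Tiparp (-1.54 ± 0.34), G6pdx (-1.46 ± 0.22) and Gsta4 (-1.34 ± 0.19) lower. None of these 5 lists passed the list test (adjusted p = 0.157 for hypoxia, 0.0733 for cholesterol, 0.157 for the unfolded protein response, 0.621 for ATF4 and 0.0733 for NRF2). Eno1, Insig1, Fdft1, Srebf2, Hspa5 and Tiparp missed the threshold without solely cultured DMSO library 2 (adjusted p = 0.0664 to 0.145, with Phgdh 0.0680 and Slc7a11 0.171) and without library 3 (0.0533 to 0.159, with Dhcr24 0.116, Herpud1 0.0633 and Slc7a5 0.0661). Without co-cultured DMSO library 2, Dhcr24, Tiparp and Slc7a11 missed it (0.0723, 0.0535 and 0.0517), and without library 3, Slc7a11 (0.0748).

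**Figure D3:**
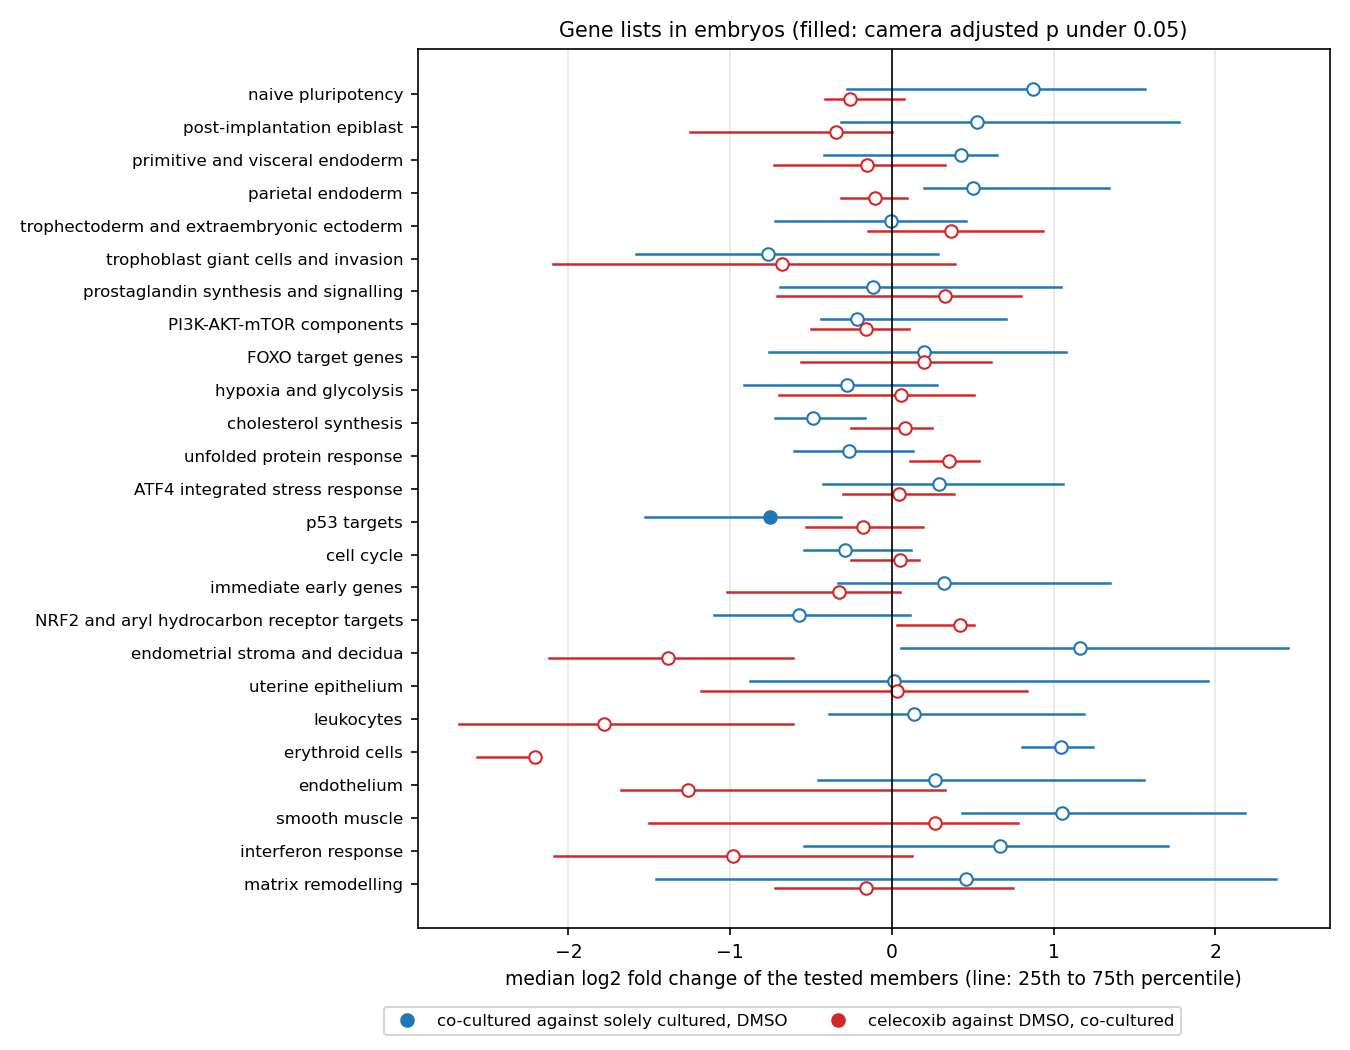
Median log2 fold change (horizontal axis) of 25 gene lists (vertical axis) for co-culture against sole culture with DMSO (blue) and for celecoxib against DMSO in co-culture (red, 1 celecoxib library). Points are medians of tested members (members at 0 in a group at their bound), lines the 25th to 75th percentile, filled points passed the list test; with library totals the fitted mean changed sign for visceral endoderm (-0.01, but 0.15 with 1 member at its bound), trophectoderm, hypoxia, cholesterol, unfolded protein response and cell cycle (blue), and for trophectoderm and unfolded protein response (red).

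Markers of cell types that endometrial tissue could leave among the embryos were also followed. For 174 genes with at least 100 CPM at DMSO implantation sites and under 1 CPM in solely cultured DMSO embryos, the median level relative to the tissue was 0.296% and 0.223% in co-cultured DMSO libraries 2 and 3. It was 0.0741% in the co-cultured celecoxib library and 0.0295% and 0.0309% in the solely cultured celecoxib libraries. Of 22 uterine epithelial genes, 4 rose and 5 fell (4 and 6 over the list alone): the transcription factor Pax8 (2.77 ± 0.24) and Calb1 (2.29 ± 0.28) rose and the keratin Krt19 fell (-2.48 ± 0.37). The genes that fell include Krt8 and Krt18, which the trophectoderm list also holds. Their fall is therefore not particular to uterine cells, and the list as a whole does not measure carry-over. Sprr2f, a member of the uterine epithelial list, held 2524 counts in co-cultured and 2 in solely cultured DMSO embryos, a ratio of 1299 (95% counting interval 359 to 10730). The ratio was 314 without co-cultured library 2, which held 2185 of these counts, and 2530 without library 3. The median of that list was 0.01 and its mean 0.88, while the test pointed down (adjusted p = 0.937). The endothelial genes Cdh5 (2.95 ± 0.48) and Pecam1 (2.35 ± 0.22) rose among 13 tested, and 0 fell, over all genes and over the list alone (adjusted p = 0.570). None of 13 endometrial stroma, 17 leukocyte, 5 erythroid and 14 smooth muscle genes passed the edgeR test, over all genes or the list alone. The medians of these 4 lists were 1.16, 0.14, 1.04 and 1.05 (adjusted p = 0.316, 0.692, 0.795 and 0.495). Of 20 interferon response genes 1 rose, over all genes and the list alone: Oas2, at 213 counts in co-cultured and 0 in solely cultured DMSO embryos, was at least 73.1-fold higher (list adjusted p = 0.621). Of 18 matrix remodelling genes, 5 rose and 4 fell (6 and 4 over the list alone; adjusted p = 0.681). They held Loxl2 higher (2.50 ± 0.41) and Timp2 (-2.69 ± 0.47), Plat and the cathepsin Ctsb (-1.77 ± 0.23) lower. Timp2 missed the threshold without solely cultured DMSO library 2 (adjusted p = 0.0526) and Loxl2 without library 3 (0.0524). For the 25 lists of this comparison the adjusted p with an estimated correlation was 0.841 or more. Intervals and bounds on counts cover counting error alone, and the p-values measure the spread between these pooled embryo and tissue samples.

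In the single co-cultured celecoxib library, Apoa1, the gene of the main protein of high-density lipoprotein, stood higher than in the 2 co-cultured DMSO libraries. Apoa1 (ENSMUSG00000032083.8, chromosome 9, 46228580 to 46230466) rose by 3.38 ± 0.36, from 1.72 ± 0.49 to 18.0 CPM, against 42.4 ± 2.13 CPM in solely cultured DMSO embryos. BC051665, a cathepsin-like gene (2.69 ± 0.27, 394 ± 41.8 to 2535 CPM), the aldehyde dehydrogenase Aldh3b2 (2.33 ± 0.26, 2.99 ± 0.47 to 15.1 CPM) and the phosphodiesterase Smpdl3a (2.11 ± 0.23, 10.1 ± 1.42 to 43.6 CPM) also rose. Pfpl, a gene related to the pore-forming perforins, fell by 4.27 ± 0.46, from 8.72 ± 0.78 to 0.450 CPM (21 counts in the celecoxib library). BC051665 has close paralogs, so its counts depend on how shared reads were divided. Neurl4 (-2.10, adjusted p = 0.222) and Myo6 (-1.45, adjusted p = 0.227), with the next smallest p among lower genes, did not pass.

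These 4 higher genes and 1 lower gene, of 19455, were those that passed (edgeR, adjusted p = 0.0456 each; 2015 genes at an unadjusted p under 0.05). The comparison set 1 celecoxib library against 2 DMSO libraries and assumed that the lone library varies like the other groups. The count was 0 with library totals (which moved the median of all genes by -0.281), a stricter filter, the compared groups alone or limma on filtered TPM, 590 with no filter and 365 by DESeq2. Without co-cultured DMSO library 2 or 3, the comparison set 1 library against 1, and all of the spread came from the solely cultured groups. Libraries within those groups correlated more closely (0.962 and 0.968) than the co-cultured DMSO libraries did (0.953). Calls from those fits therefore do not show that these 5 genes are stable. With a term for the replicate number, 11 genes passed, and with DESeq2 size factors 4, Smpdl3a being lost (adjusted p = 0.0512). Of the list members only Apoa1 passed over all genes, and no list passed the list test (smallest adjusted p = 0.0617; 0.820 or more with an estimated correlation). The smallest was shared by trophectoderm genes (median 0.37; mean 0.21, or -0.06 with library totals), the unfolded protein response (median 0.35; mean 0.26, or -0.03 with library totals) and leukocyte genes (median -1.78; 4 of 17 at 0 in a group). When adjusted over the list alone, some trophectoderm genes were higher, among them Krt18 (1.07), Krt8 (0.99), Ascl2 (1.38) and Tfap2a (0.95). So were some uterine epithelial and trophoblast giant cell genes, though the uterine epithelial list shares Krt18 and Krt8 with the trophectoderm list. Some post-implantation epiblast genes were lower. The lists of primitive and visceral endoderm, immediate early genes and hypoxia held members of both directions. Phlda2 (1.93, adjusted p = 0.111), Pou3f1 (-2.19, adjusted p = 0.222), Ndrg1 (1.43, adjusted p = 0.176) and Hpgd (1.38, adjusted p = 0.418) did not pass over all genes. For 11 lists in this comparison, such as hypoxia, cholesterol and cell cycle, the mean was negative while the list test pointed up.

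In solely cultured embryos, no gene passed between celecoxib and DMSO. The genes with the smallest p, none of which passed, were the germ-cell RNA-binding protein gene Dazl (1.87 ± 0.37), the acute-phase gene Saa3 (1.51), Rcn1 (0.84), Apoa1 (-1.20 ± 0.30), Myo18a (-1.22) and the iron exporter Slc40a1 (-0.94). At an unadjusted p under 0.05 by edgeR stood 1244 genes, where 973 are expected without change in each embryo comparison. The count of genes that passed was 0 by edgeR (n = 2 per group, smallest adjusted p = 0.746) and by limma. It was 88 by DESeq2, 284 with no filter and 12 without solely cultured DMSO library 2. Library totals moved the median by -0.143. No list passed (smallest adjusted p = 0.104, parietal endoderm).

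Co-culture of celecoxib-treated embryos was accompanied by lower Adh1, Pfpl and Aqp9 and higher Prnd, Rpgrip1 and Gadd45a. Adh1 fell by 7.32 ± 0.59 (356 ± 177 to 2.23 CPM), and Pfpl (-5.25 ± 0.48) and Aqp9 (-3.87 ± 0.37) fell too. Prnd, a gene related to the prion protein gene (4.26 ± 0.67), Rpgrip1 (2.95 ± 0.43) and Gadd45a (2.94 ± 0.40) rose. Of 19 p53 targets 0 rose and 3 fell (1 and 8 over the list alone): the cell cycle inhibitor Cdkn1a (-2.87 ± 0.47), Eda2r (-3.43 ± 0.59) and Trp53inp1 (-1.85 ± 0.26). This list passed the list test (mean -0.91, 15 of 19 negative, adjusted p = 0.00266; mean -0.76 with library totals). So did the cell cycle list, with 24 of 28 genes negative (mean -0.43, or -0.28 with library totals; adjusted p = 0.00278), 0 called over all genes and 4 lower over the list alone. With an estimated correlation the adjusted p was 0.825 for both. With library totals leukocyte genes passed too, pointing down (mean -1.97, adjusted p = 0.103; -1.82 and 0.0388 with totals). With the 4 of 17 members that had a group at 0 at their bound, the mean was -1.08. G6pdx fell (-1.72 ± 0.28), and Pax8 (1.65 ± 0.27) and the endothelial gene Pecam1 (1.44 ± 0.25) rose.

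In total 57 genes were higher and 79 lower (41.9% higher; edgeR, 1 co-cultured against 2 solely cultured libraries, the lone library again assumed to vary like the others), or 155 and 70 with library totals (68.9% higher, median moved by 0.149). Without solely cultured celecoxib library 2 or 3 only 1 gene passed. Adh1 was the 1 named gene kept, and the others had an adjusted p of 0.0691 to 0.274 and 0.0866 to 0.226. If replicate numbers mark shared donors, which the labels do not say, a term for them is called for. With it Prnd, Cdkn1a, Eda2r, G6pdx, Pax8 and Pecam1 missed the threshold (adjusted p = 0.0507 to 0.0562), as did Eda2r and Pecam1 with DESeq2 size factors (0.0512 each). DESeq2 called 1969 genes and a fit of the compared groups alone 1724. The co-culture differences with DMSO and with celecoxib, which share no library, correlated across the 19455 genes (r = 0.390, Spearman 0.554; -0.0252 to 0.0222 in 30 simulations without change), a relation chosen after the values were seen. The simulations drew each gene independently, so their range leaves out variation that genes share. Of the 57 genes higher with celecoxib, 53 were among the 1122 higher with DMSO (3.29 by chance), and of the 79 lower, 73 were among the 2021 (8.21 by chance); genes are not independent of each other.

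Celecoxib and co-culture differences were compared directly. The celecoxib differences in co-cultured and solely cultured embryos, with no library in common, correlated weakly (r = 0.214, Spearman 0.298; -0.0283 to 0.0252 in the simulations). Without solely cultured DMSO library 3, r was 0.0310. The celecoxib difference in co-culture ran against the co-culture difference with DMSO (r = -0.431, Spearman -0.503); both use the co-cultured DMSO libraries, and simulations without change gave -0.398 to -0.340. The covariance of -1.38 lay beyond the simulated -0.513 to -0.413. The simulations drew each gene independently. Their ranges therefore leave out variation that genes share and do not bound r or the covariance without change. With the 2 co-cultured DMSO libraries divided between the comparisons, so that none was shared, r on log2 CPM was -0.211 and -0.294 (-0.505 undivided). The 4 genes higher with celecoxib in co-culture (Apoa1, BC051665, Aldh3b2 and Smpdl3a) were among the genes lower in co-culture, while Pfpl was lower in both. No chance value is given for this overlap, since both comparisons use the co-cultured DMSO libraries.

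In the test of the interaction, Apoa1 (4.57), BC051665 (3.15) and Aldh3b2 (3.08) had the smallest adjusted p, 0.0629 each, and Pfpl stood at -3.95 (adjusted p = 0.0998), Myo6 at -1.56 (0.531) and Plxnb2 at -2.03 (0.543). No gene passed by edgeR (1170 at an unadjusted p under 0.05; the co-cultured celecoxib group is 1 library, assumed to vary like the others), against 140 by DESeq2, 0 or 1 by limma, 243 with no filter, and 28 or 19 without co-cultured DMSO library 2 or 3. Library totals moved the median by -0.136. The list test of the interaction pointed down, with adjusted p = 0.0212 each, for post-implantation epiblast and leukocyte genes. Of the epiblast genes 15 of 19 were negative (median -0.63; 0 higher and 1 lower over the list alone), and of the leukocyte genes 13 of 17 (median -1.47; 5 with a group at 0). The median level of endometrial genes, given above, was also lower in the co-cultured celecoxib library (0.0741%) than in the co-cultured DMSO libraries (0.296% and 0.223%). With an estimated correlation the adjusted p was 0.903 for both. Neither passed without solely cultured DMSO library 3 (0.429 and 0.171), solely cultured celecoxib library 2 (0.156 and 0.230) or co-cultured DMSO library 2 (0.0764 each).

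At implantation sites, celecoxib was accompanied by higher Ccl2, P2ry14 and Spon2 and lower Fga and Fgg. Ccl2, a chemokine that attracts monocytes (ENSMUSG00000035385.5, chromosome 11, 82035571 to 82037453), rose by 4.09 ± 0.36, from 4.25 ± 0.05 to 72.6 ± 32.1 CPM (adjusted p = 0.0318), but missed the threshold without any 1 of the 4 libraries (0.0680 to 0.266). Also higher were the nucleotide-sugar receptor P2ry14 (3.62 ± 0.32, 9.86 ± 1.01 to 121 ± 50.1 CPM), the matrix protein Spon2 (2.40 ± 0.15), the collagen gene Col6a4 (2.29 ± 0.17), the phosphatase Ptpn5 (1.66 ± 0.20) and the laminin gene Lama3 (1.27 ± 0.12). The neighbouring fibrinogen genes Fga (ENSMUSG00000028001.16, chromosome 3, 83026076 to 83033627; -3.91 ± 0.42, 107 ± 56.9 to 7.13 ± 1.24 CPM) and Fgg (chromosome 3, 83007724 to 83015049; -3.23 ± 0.26, 25.5 ± 0.46 to 2.71 ± 0.49 CPM) fell. So did Slc46a2 (-2.95 ± 0.30), the extracellular matrix protein gene Coch (-2.91 ± 0.32, 203 ± 89.3 to 27.0 ± 3.25 CPM), the anion exchanger Slc26a6 (-2.53 ± 0.23) and Csdc2 (-2.23 ± 0.23).

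**Figure D4:**
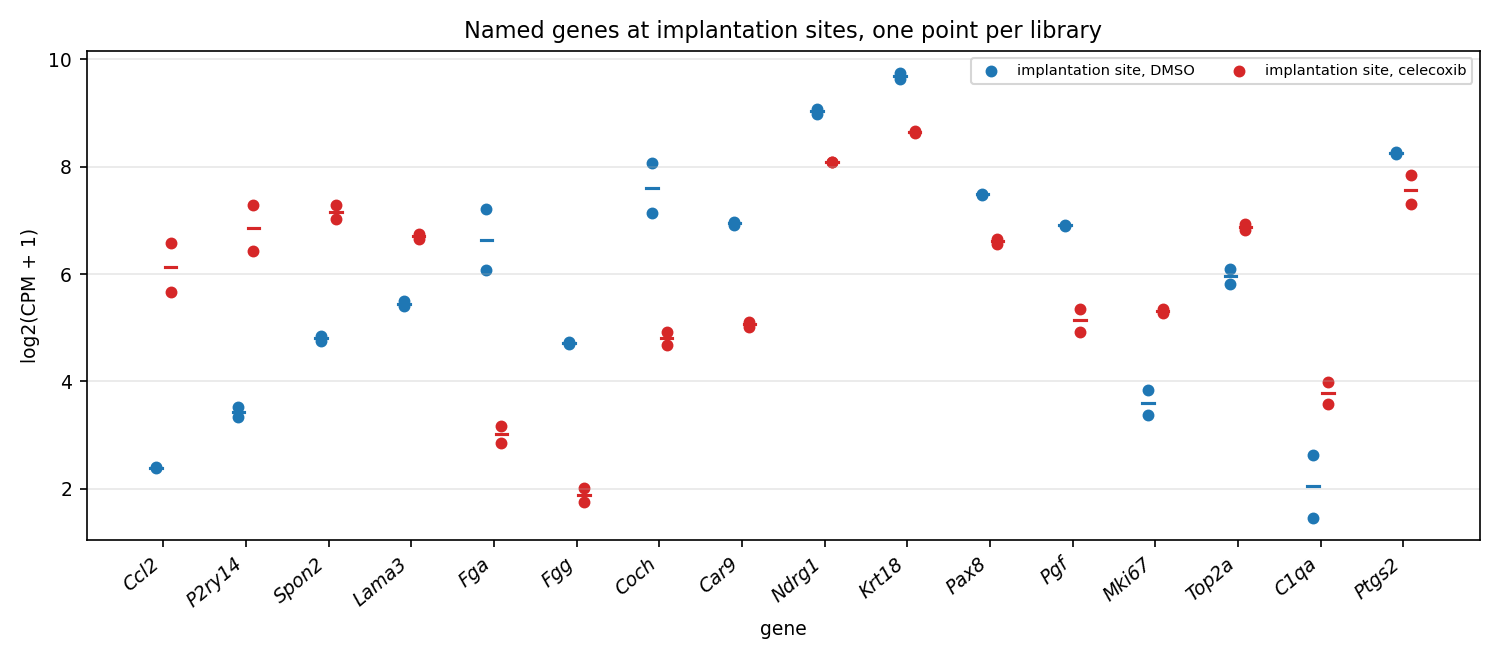
Levels of 16 genes in the 4 implantation-site libraries, as log2(CPM + 1) on the vertical axis and by treatment on the horizontal axis. Each point is 1 library and each short line a group mean of 2; Ccl2 stood at 4.25 CPM with DMSO and 72.6 CPM with celecoxib.

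Of 16725 genes tested, 2771 had an unadjusted p under 0.05, where 836 are expected without change. After adjustment 16 were higher and 50 lower (edgeR, n = 2 per group, 2 residual degrees of freedom). The count was 0 without celecoxib library 2 or 3, where the 18 named genes had an adjusted p of 0.0998 to 0.288 and 0.266 to 0.545. It was 333 or 888 without DMSO library 2 or 3, where Ccl2 (0.0925 and 0.0680) and P2ry14 (0.124 and 0.0827) missed the threshold. DESeq2 called 1308 genes and limma on TPM 301, or 0 with no filter.

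Genes of the cell cycle and of cholesterol synthesis lay higher with celecoxib as groups at the preset correlation. With an estimated correlation the adjusted p was 0.573 for each of the 3 lists described here. All 28 cell cycle genes had positive values (mean 0.96, median 0.91, list adjusted p = 2.89e-12); 0 passed over all genes and 18 were higher over the list alone. Examples were the proliferation marker Mki67 (1.78 ± 0.23, 11.3 ± 2.77 to 38.7 ± 1.40 CPM; adjusted p = 0.0614), Bub1b (1.44 ± 0.25), the helicase subunit Mcm4 (0.93 ± 0.13) and the topoisomerase Top2a (0.92 ± 0.14). Of 21 cholesterol synthesis genes 19 were positive (mean 0.37, median 0.41, list adjusted p = 0.000154), with 0 called over all genes and 11 higher and 1 lower over the list alone, among them Idi1 (0.97 ± 0.12, adjusted p = 0.0586), Insig1 (0.76) and Sqle (0.74). NRF2 and aryl hydrocarbon receptor targets lay higher too (17 tested; mean 0.85, or 0.64 with Cyp1a1 at its bound; median 0.26; adjusted p = 0.0260), 0 over all genes and 7 over the list alone, such as the quinone reductase Nqo1 (1.98 ± 0.45) and Txnrd1 (0.61 ± 0.09). Cyp1a1, the classical aryl hydrocarbon receptor target, held 325 counts with celecoxib and 0 with DMSO, at least 130-fold higher (adjusted p = 0.0635). The NRF2 list missed the threshold without DMSO library 2 (adjusted p = 0.0916) and celecoxib library 2 (0.0845). Beside these groups, the markers of leukocytes were higher (mean 0.95) and those of epithelium lower (mean -0.56).

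Leukocyte, inflammatory and interferon genes lay higher at the preset correlation, with adjusted p = 0.573 for each list with an estimated correlation. Of 22 leukocyte genes 18 were positive (mean 0.95, median 0.83, adjusted p = 0.000154); 0 passed over all genes and 3 were higher over the list alone. Values were 2.23 for the macrophage marker Adgre1, 2.02 ± 0.37 for the integrin Itgam (3.07 ± 0.63 to 12.5 ± 3.76 CPM) and 1.93 for the complement gene C1qb. Of 26 inflammatory cytokines and NF-kB targets 18 were positive (mean 0.88, median 0.43, adjusted p = 0.00792), with Ccl2 called over all genes and 5 higher over the list alone. The chemokines Ccl7 (3.81 ± 0.70) and Cxcl1 (2.38 ± 0.49) did not pass over all genes. Of 21 interferon response genes 19 were positive (mean 0.38, median 0.30, adjusted p = 0.00368), with 0 called over all genes and 2 higher and 1 lower over the list alone, such as Stat1 (0.53), Isg15 (1.09) and Rsad2 (-1.18). The inflammatory and interferon lists missed the threshold without DMSO library 2 (means 1.07 and 0.32) and without celecoxib library 3 (means 0.49 and 0.22).

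Hypoxia, epithelial, FOXO and unfolded protein response genes lay lower at the preset correlation, with adjusted p = 0.573 for each list with an estimated correlation. Of 26 hypoxia and glycolysis entries 24 were negative (mean -0.44, median -0.32, adjusted p = 4.98e-05), and 3 fell (10 over the list alone). These were the carbonic anhydrase Car9 (-1.91 ± 0.12, 122 ± 3.37 to 32.4 ± 1.49 CPM), the prolyl hydroxylase Egln3 (-1.29 ± 0.11) and Ndrg1 (-0.95 ± 0.09). Of 21 uterine epithelial genes 15 were negative (mean -0.56, median -0.55, adjusted p = 0.000579), and 2 fell (10 over the list alone), Krt18 (-1.05 ± 0.09, 823 ± 48.7 to 399 ± 8.73 CPM) and Pax8 (-0.88 ± 0.10, 178 ± 2.42 to 96.8 ± 4.86 CPM). The EGF-family ligand Areg stood at -2.15 ± 0.28 (adjusted p = 0.0624). Of 20 FOXO targets 18 were negative (mean -0.42, median -0.38, adjusted p = 0.00202), 0 called over all genes and 4 lower over the list alone, with Pdk4 at -2.21, Gadd45a at -0.68 ± 0.11 and Bnip3 at -0.57 ± 0.10. Of 18 genes of the unfolded protein response 17 were negative (mean -0.35, median -0.26, adjusted p = 0.00361), 0 called over all genes and 1 lower over the list alone, Sdf2l1 (-0.96 ± 0.15). Without DMSO library 2 the unfolded protein response list missed the threshold, and its mean was -0.16. The 10 lists called at implantation sites kept their calls with library totals.

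Among the other lists Pgf, a placental growth factor of the VEGF family, fell (-1.78 ± 0.18, 119 ± 0.77 to 34.7 ± 7.38 CPM; adjusted p = 0.0346). It was 1 of 20 angiogenesis genes (2 higher and 3 lower over the list alone; list median -0.22, adjusted p = 0.105). No other member passed over all genes. Decidualization genes (28 tested, 4 higher and 4 lower over the list alone, median -0.34, adjusted p = 0.0963) held values of -2.05 for Cebpb, -0.87 for Hand2 and 1.16 for Angpt2. Attachment and receptivity genes (26 tested, 1 and 10 over the list alone, median -0.13, adjusted p = 0.160) held Ltf at -1.18 and Socs3 at 0.78. Prostaglandin genes (23 tested, 0 and 2 over the list alone, median -0.07, adjusted p = 0.570) held the receptor Ptger2 at -0.90 (adjusted p = 0.0877) and the transporter Abcc4 at -0.69. Trophoblast genes (13 tested) had 0 higher and 2 lower over the list alone (median -0.32, adjusted p = 0.0963), PI3K-AKT-mTOR components 0 and 2 of 27 (-0.07, adjusted p = 0.147). The counts were, for p53 targets, 0 and 2 of 20 (-0.12, adjusted p = 0.142), ATF4 genes 8 and 1 of 22 (0.31, adjusted p = 0.0677) and matrix remodelling genes 1 and 1 of 24 (-0.16, adjusted p = 0.615). Immediate early genes had 0 and 0 of 18 (median 0.02, adjusted p = 0.805) and embryonic cell markers 0 and 0 of 7 (0.22, adjusted p = 0.653). Smooth muscle genes (10 tested, 1 and 3 over the list alone) had a median of -0.20 and a mean of 0.42, with the test pointing down (adjusted p = 0.641; Tagln -1.22, adjusted p = 0.0504). List medians were -0.58 for 5 erythroid genes (adjusted p = 0.131) and -0.10 for 16 endothelial genes (adjusted p = 0.226).

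**Figure D5:**
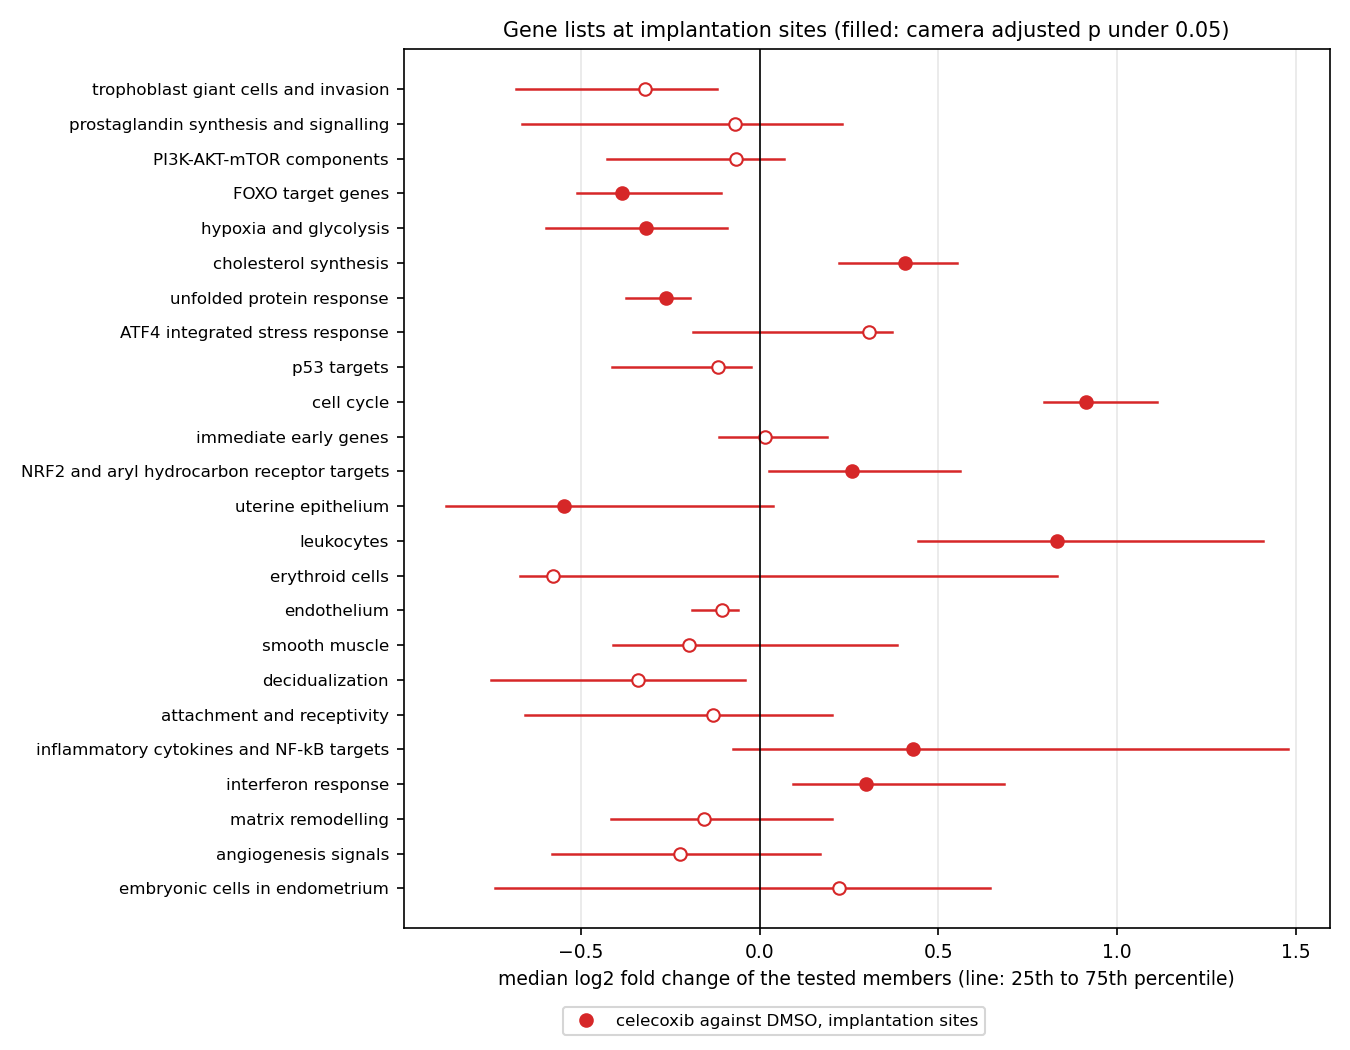
Median log2 fold change (horizontal axis) of 24 gene lists (vertical axis) at implantation sites, celecoxib against DMSO, n = 2 libraries each. Points are medians of the tested members, with members at 0 in a group set at their bound, lines run from the 25th to the 75th percentile, and the 10 filled points passed the list test.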

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

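The tests on trophectoderm share, on scaling as the source of the excess of lower genes and on epithelial share were chosen after the result was seen.

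Between co-cultured and solely cultured DMSO embryos, 1122 genes were higher and 2021 lower. RNA carried over from endometrium, taken at the same share (0.26%) for every gene, accounts for 0.163% of the rise of the median higher gene. It accounts for over 50% of the rise in 4 of the 1122 (Gjb2, Ltf, Igfbp4 and Trf, 0.357%). This argues against carry-over in even shares as the cause of the higher genes as a set. The shares were uneven, however. In co-cultured libraries 2 and 3 Sprr2f stood at 61.7 and 7.65 CPM against 4366 at DMSO implantation sites, and Col3a1 at 0.282 and 0.293 against 2900. Carry-over weighted to 1 cell type, such as epithelium, is not covered by this test. A lower share of trophectoderm-derived cells cannot be told apart from other changes: the median of the trophectoderm list lay 1.26 above that of the lower genes (SD 1.02), themselves picked for being lower, but that of the trophoblast giant cell list, also of that lineage, only 0.501 above (SD 2.15, 15 of 21 negative), and Krt8, Krt18, Ascl2 and Id2 fell. Scaling between libraries cannot be told apart either for the called genes as a set, since the 74.3% kept with library totals (1122 of 1122 higher and 1213 of 2021 lower) lay between the bars set for scaling as the cause (under 50%) and not the cause (over 80%). With library totals 58.2% of calls were higher, against 35.7% with TMM. The upward move of all genes shifts calls toward higher by itself. This share therefore cannot tell whether scaling caused the excess of lower over higher genes. A response to the endometrium, the difference the design names, stays open and untested.

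In co-culture, the celecoxib differences ran against the co-culture differences. With no library shared, r was still -0.211 and -0.294, so a shared library is not needed for a negative r. No range of r without change was available for genes that vary together. Deviations of same-numbered libraries from their group means, with no library in common, correlated at 0.163 between co-cultured and solely cultured DMSO embryos. These values of r therefore cannot tell the relation from chance. Whether the single celecoxib library departs from its group cannot be told apart from an effect of celecoxib, because the group has 1 library (first component 39.29, between the solely cultured and co-cultured DMSO libraries).

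At implantation sites with celecoxib, cell cycle and leukocyte genes lay higher and epithelial genes lower, calls that were lost with an estimated correlation (adjusted p = 0.573 for each list). A smaller share of epithelium in the tissue pieces would by itself raise all other cell types alike. Leukocyte genes lay 1.05 above endothelial genes (SD of list members 0.981). This SD measures scatter among genes, not the spread between mice, so the margin cannot decide whether a smaller share was the only source. Centred library means of leukocyte genes were -0.824 and -0.181 with DMSO and 0.284 and 0.721 with celecoxib. Those of endothelial genes were -0.0169 and 0.121 with DMSO and -0.0543 and -0.0494 with celecoxib. The comparison also cannot tell whether the lower epithelial genes came from less epithelium, which can go with more leukocytes. A single aberrant DMSO library is argued against by the mean of the cell cycle list, 0.747 and 1.28 without either DMSO library (0.96 with both); leukocyte genes stood at 0.713 and 1.39, epithelial genes at -0.617 and -0.475. A change in leukocytes or proliferation with celecoxib, or a difference between recipient mice, may underlie the pattern and was not tested.

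The interaction of celecoxib and co-culture passed the list test for post-implantation epiblast (adjusted p = 0.0212) and for leukocytes (adjusted p = 0.0212). With an estimated correlation the adjusted p was 0.903 for both, and neither passed without solely cultured DMSO library 3 (0.429 and 0.171), solely cultured celecoxib library 2 (0.156 and 0.230) or co-cultured DMSO library 2 (0.0764 each). The median level of endometrial genes was also lower in the co-cultured celecoxib library (0.0741%) than in the co-cultured DMSO libraries (0.296% and 0.223%). For 4 lists, the difference in co-cultured embryos (1 celecoxib library) lay opposite to that at implantation sites in every library, and this was not tested: FOXO targets 0.0368 against -0.403, unfolded protein response 0.282 against -0.335, leukocytes -1.35 against 1.01, and interferon response -0.687 against 0.423. For FOXO targets the celecoxib library (0.1495) was level with co-cultured DMSO library 2 (0.1493) and the mean fold change was -0.05 (-0.32 with library totals), and for the unfolded protein response the mean of 0.26 turned to -0.03 with library totals.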

How the results depend on the processing

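None of the tests in this part were chosen after the result was seen. For co-culture with DMSO (3143 genes), DESeq2 called 4744, limma on unfiltered TPM 1328, and leaving out libraries gave 1190 to 3331; the list calls (1) became 8 with no filter, 1 to 2 with a library left out and 0 with an estimated correlation. For celecoxib in co-culture (5 genes), the count was 0 with library totals, 0 with a stricter filter, 0 with the compared groups alone, 590 with no filter, 11 with the replicate term, 25 to 176 with a library left out, 365 by DESeq2, and 0, 0 and 131 by limma (TPM + 1, TPM + 0.1, no filter); list calls (0) became 3 with no filter, 3 with the replicate term, 2 with the compared groups alone and 1 to 3 with a library left out. For celecoxib in sole culture (0), it was 284 with no filter, 0 to 12 with a library left out and 88 by DESeq2, and list calls (0) became 2 with no filter and 0 to 3 with a library left out. For co-culture with celecoxib (136), it was 225 with library totals, 1692 with no filter, 207 with a stricter filter, 1724 with the compared groups alone, 1 to 1 with a library left out and 1969 by DESeq2; its list calls (2) became 3 with library totals (leukocytes, adjusted p = 0.0388), 3 with no filter, 3 with the replicate term, 3 to 4 with a library left out and 0 with an estimated correlation. For the interaction (0), it was 243 with no filter, 140 by DESeq2, 1 by limma (TPM + 0.1) and 0 to 28 with a library left out; list calls (2) became 1 with no filter, 0 to 2 with a library left out and 0 with an estimated correlation. At implantation sites (66), it was 269 with no filter, 112 with a stricter filter, 40 with the replicate term (32 shared; Lama3, Fga, Coch, Slc26a6, Ndrg1, Krt18 and Pax8 missed the threshold, adjusted p = 0.0551 to 0.0777, and the NRF2 list at 0.0526), 0 to 888 with a library left out, 1308 by DESeq2, and 301, 266 and 0 by limma; list calls (10) ran from 7 to 11 with a library left out and became 0 with an estimated correlation. The correlation of the 2 celecoxib differences (0.214) ran from 0.0310 to 0.245 with a library left out, and that of co-culture with celecoxib in co-culture (-0.431) from -0.525 to -0.391. With size factors, no filter, the replicate term, the compared groups alone or a library left out, of 908 values of called named genes 748 kept their side of the threshold and 160 lost it; of 3671 uncalled, 246 gained it; of 123 values of called lists (with the estimated correlation also) 30 lost it, and of 1116 uncalled 36 gained it; 0 of these reversed. With library totals all called lists kept their call, though the mean of some uncalled ones turned. Named genes were not tallied with library totals, and neither genes nor lists with the stricter filter, DESeq2 or limma. Except where fewer libraries were fitted, the cause was not tested. Deviations of same-numbered libraries from their group means correlated at 0.163 between co-cultured and solely cultured DMSO embryos, and at -0.0191 and -0.0442 in the other embryo pairs and 0.0487 in endometrium. With the replicate term, 6 of the 12 named genes called for co-culture with celecoxib missed the threshold (Prnd, Cdkn1a, Eda2r, G6pdx, Pax8 and Pecam1, adjusted p = 0.0507 to 0.0562). Leaving out the table term, or fitting 1 table, gives the model used, and alternatives for tissue between implantation sites were not run. Depth limits genes near 0 in a group (Oas2, Cyp1a1, Sprr2f, Pfpl and Ptgs2 in embryos); for the others the 2 or 3 residual degrees of freedom limit the tests.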

Other observations

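The 2 gene lists tested here and all genes named here were chosen after the gene values were seen.

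Of 49 genes of lysosomal enzymes and their activators, 22 fell and 0 rose in co-cultured DMSO embryos relative to solely cultured ones (44.9% lower, against 10.3% of other genes; 24 lower and 1 higher over the list alone), and 34 were negative. Among them were the acid sphingomyelinase Smpd1 (-4.79 ± 0.28), the cathepsins Ctsc (-3.49 ± 0.23) and Ctsd (-2.35 ± 0.20), the galactosidases Glb1 (-3.36 ± 0.29) and Gla (-2.55 ± 0.28) and the hexosaminidase Hexa (-2.34 ± 0.20). The list median was -0.58 (adjusted p = 2.38e-07 over 2 lists and 6 comparisons; 0.143 with an estimated correlation; median -0.30 and 21 lower with library totals), and 20 to 21 fell with any of the 4 libraries left out. With celecoxib, 7 of the 49 fell in co-culture relative to sole culture (median -0.91, adjusted p = 2.10e-08; 0.143 with an estimated correlation), but 0 without either solely cultured celecoxib library (list adjusted p = 4.38e-07 and 1.91e-07). In celecoxib against DMSO in co-culture, with 1 celecoxib library, 9 were higher over the list alone and 0 over all genes (median 0.27, or -0.01 with library totals, fitted mean -0.07; the test pointed up, adjusted p = 0.00694; 0.249 with an estimated correlation). The list was put together from known lysosomal proteins, after some of these values had been seen, so it is not independent evidence.

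Of 29 genes of mitochondrial fatty acid oxidation, 18 fell and 0 rose in co-cultured DMSO embryos (62.1%, against 10.3% of other genes; 22 lower over the list alone). Among them were the carnitine transporter Slc22a5 (-4.27 ± 0.44), the carnitine carrier Slc25a20 (-2.37 ± 0.21) and the acyl-CoA dehydrogenases Acadl (-2.55 ± 0.27) and Acadvl (-2.12 ± 0.20). This list, like the lysosomal one, was chosen after the gene values were seen, so it is not independent evidence. For both lists the other genes were not matched for abundance, and the adjustment does not cover lists that could have been chosen instead. The list mean was -1.10 (adjusted p = 2.10e-08; 0.178 with an estimated correlation; mean -0.81 and 15 lower with library totals), and the number lower was 11 without solely cultured DMSO library 2. With celecoxib, 3 of the 29 fell in co-culture relative to sole culture (mean -0.87, adjusted p = 1.49e-07; 0.178 with an estimated correlation), but 0 without either solely cultured celecoxib library. In celecoxib against DMSO in co-culture 0 passed, over all genes or the list alone, and the list pointed up (median 0.41, or 0.13 with library totals; adjusted p = 0.000393; 0.271 with an estimated correlation). For the interaction the list tests of lysosomal enzymes and fatty acid oxidation gave adjusted p = 0.0407 and 0.0110 (0.278 and 0.326 with an estimated correlation), without solely cultured DMSO library 2 0.182 and 0.146, and without solely cultured celecoxib library 3 0.106 and 0.0779. The lysosomal list also missed the threshold without solely cultured celecoxib library 2 (0.0725), without co-cultured DMSO library 3 (0.116) and with the replicate term (0.0949). Celecoxib in sole culture gave 0.369 and 0.219, and lysosomal enzymes at implantation sites 0.369. At implantation sites the fatty acid oxidation list pointed up with celecoxib (mean 0.26, adjusted p = 0.00943; 0.271 with an estimated correlation), with 0 higher and 1 lower over all genes and adjusted p = 0.0732 without DMSO library 2 and 0.0568 without celecoxib library 3. Other genes higher in co-cultured DMSO embryos were the growth factor Igf2 (2.37 ± 0.30), Podxl (2.74) and the metallothioneins Mt1 (1.62) and Mt2 (1.82).

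At implantation sites the immunoglobulin genes Igha (-4.92 ± 0.24, adjusted p = 0.0205) and Igkc (-4.77 ± 0.43, adjusted p = 0.0322) fell with celecoxib, and reads of immunoglobulin genes are shared among similar segments. Also lower were the histamine-producing enzyme Hdc (adjusted p = 0.0362), Lrat (-1.43 ± 0.13) and Cyp26a1 (-1.15 ± 0.09), which store and degrade retinoids, the itaconate-producing enzyme Acod1 (-1.35 ± 0.15) and Wnt11 (-1.47 ± 0.16). Higher were Aldh1a2, which makes retinoic acid (1.17 ± 0.12), and the matrix genes Fbn1 (1.23 ± 0.10) and Olfml3 (1.18 ± 0.12). Calls at these sites were 0 without celecoxib library 2 or 3.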
